A study of Canis lupus familiaris with 17 samples.

How the data were processed

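RNA from formalin-fixed, paraffin-embedded soft tissue sarcomas of pet dogs was measured on the nCounter Canine IO panel, which counts colour-barcoded probes hybridized to RNA without amplification. The panel holds 780 endogenous, 20 housekeeping, 8 negative control and 6 positive control probes. The treated tumours had received intratumoral IL-2 and IL-12 fused to a collagen-binding protein, so that the cytokines stay in the tumour. Per the labels, 3 tumours were excised on day 2 after 1 dose, 3 on day 8 after 1 dose, and 4 on day 8 after a second dose on day 6. The other 7 tumours were archived untreated sarcomas. Archiving therefore went with treatment in every comparison with untreated and cannot be told apart from it. Each sample came from a different dog, so every comparison is between animals.

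Per the file headers and the labels, the deposited raw files hold counts per probe, exported from nSolver without normalization. The deposited value table holds the authors' normalized signal. The nSolver version and the normalization steps are not given in the sources used here and were read from the values. Over probes with more than 40 raw counts, each value in that table was the raw count times 1 factor per sample, from 0.898 to 11.6. The factor times the sample's housekeeping geometric mean was 636 to 639 in every sample, so the factor followed the housekeeping probes. In each sample 22 to 169 probes shared the lowest value, a floor whose rule is not given. In the 4 second-dose and 7 untreated samples, and in none of the 6 single-dose samples, 663 probes with enough counts also showed a factor per probe, as a calibration between reagent lots would give. These factors had an SD of 0.06 log2 and lay between -0.23 and 0.39. The labels name no reagent lot, cartridge, lane, field of view ratio or binding density, so the cartridge could not be added to a model. A further deposited normalized table, whose columns matched no label, was not used.

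Of the 800 endogenous and housekeeping probes, 777 were named by gene symbol or gene identifier through the RefSeq gene table of the UU_Cfam_GSD_1.0 dog genome. The transcript accession of the probe was found there for 223. Probes named by a LOC identifier numbered 30, and 4 of these had a current symbol. Probes were counted as designed on the panel, and no sequence was aligned.

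The main test was edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, robust) on the raw endogenous counts, with the 4 groups of 17 samples in 1 model. The effective library size was the geometric mean of the 20 housekeeping probes. A probe was tested when its count passed the mean plus 2 SD of the sample's negative controls in at least 3 samples. That left 724 probes and removed 56. The comparison of tumour types among the 7 untreated samples tested 676 probes in a model of its own. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and fold changes are log2 with a standard error (SE). This SE was worked back from the test, as the absolute log2 change over the square root of F, so it adds nothing to the p-value. Normalized counts are raw counts scaled to the mean housekeeping level, given as mean and SD over tumours.

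Fixed lists, 25 in number, covered T cells, cytotoxic effectors, NK cells, B and plasma cells, macrophages and monocytes, dendritic cells, neutrophils, mast cells, regulatory and checkpoint genes, the interferon-gamma response and the type I interferon response. Others covered MHC class I and class II presentation, the IL-2 and IL-12 pathway, T cell chemokines and receptors, acute inflammation, complement, proliferation, endothelium and angiogenesis, fibroblasts and matrix, hypoxia and glycolysis, and apoptosis. The last were Schwann cell and neural markers, pericyte and smooth muscle markers, and skin, fat and skeletal muscle markers. Lists were tested with fry of limma 3.58.1 on the same model, adjusted over 175 tests. Fry tests whether a list's genes move, on balance, 1 way, and does not compare the list with other genes. The camera test, which does, was run with a preset correlation of 0.01 and with an estimated correlation. With the preset it called 53 lists over all comparisons, 42 higher and 11 lower, and kept 32 of the 56 fry calls. With the estimate it called 0. Each list was also scored per tumour as the mean of log2(normalized count + 1) over its tested members. Scores were compared by an exact two-sided permutation test, with 100000 resamples for all treated against untreated, adjusted over 100 tests. The smallest p is 0.00833 for 3 against 7 tumours and 0.00303 for 4 against 7. Some genes sit in more than 1 list, such as IDO1, CXCL10, PSMB8 and CD274.

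The comparisons, the tests, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule named, for each comparison with untreated, the 10 largest called rises and falls with a mean of at least 50 normalized counts in the higher group. For the other comparisons it named the 5 largest, and where no gene was called, the 3 with the smallest p in each direction. It added 24 fixed genes and the 2 members of each list with the smallest p. A gene outside the rule is named as chosen after its values were seen. Some genes that the rule picks are not reported here.

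Alternatives were TMM and DESeq2 median-of-ratios scaling in the same model, DESeq2 1.42.0 (Wald test), and limma (trend, robust) on log2(value + 1) of the deposited normalized table. Others were subtraction of the negative control mean, no filter, filterByExpr, sarcoma type as a covariate, peripheral nerve sheath tumours only, the replicate letter as a replicate block, only the groups compared, and each sample left out in turn. The covariate for sarcoma type separated perivascular wall tumours from all others. It did not adjust for the myxosarcoma (day 2 replicate B) or the fibrosarcoma (second-dose replicate D). Leaving out the 2 libraries with the fewest counts, using only the housekeeping probes clear of background, and applying the authors' probe factors were chosen after seeing the data. List tests after background subtraction and without those 2 libraries were also added then.

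The test was checked on simulated data with 200 of 724 genes changed, over 5 runs. At a 4-fold change it recovered 57.9% of changed genes for day 2 against untreated, 65.7% for day 8, 73.7% for the second dose and 92.5% for all treated. At a 2-fold change these shares were 9.85%, 10.7%, 19.4% and 39.7%. Recovery at a 4-fold change was 41.8% for day 8 against day 2, 52.2% for second dose against day 2, 53.1% for second dose against day 8, and 52.2% for tumour type. Unchanged genes made up 2.52% to 3.58% of the calls. Genes were simulated as independent, with rises and falls at random, so these shares may not hold in the tumours. There, untreated replicates A, C and G against the other untreated tumours gave 49 calls. A simulated list with a 4-fold shift was recovered in 5 of 5 runs in each comparison.

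Scores, tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.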

Results

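Counts were obtained for 17 canine soft tissue sarcomas: 7 untreated, 3 taken on day 2 after 1 dose, 3 on day 8 after 1 dose and 4 on day 8 after a second dose. The untreated tumours were 4 perivascular wall tumours and 3 peripheral nerve sheath tumours. The day 2 tumours were 2 peripheral nerve sheath tumours and 1 myxosarcoma, and the day 8 tumours 2 peripheral nerve sheath tumours and 1 perivascular wall tumour. The second-dose tumours were 3 peripheral nerve sheath tumours and 1 fibrosarcoma. Type and treatment were therefore not balanced.

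Endogenous totals ran from 1200521 to 1509461 counts in the untreated tumours and from 1397025 to 1571458 in the day 8 group. In the day 2 group they were 1232818, 1089862 and, in replicate C, 126997. In the second-dose group they were 1752729, 1016527, 1458022 and, in replicate D, 205118. The housekeeping geometric mean was 489 to 686 counts in untreated, 526 to 709 in day 8, 61.9 to 281 in day 2 and 55.1 to 643 in second-dose tumours. Endogenous probes above background numbered 607 to 686 per tumour, except 416 in replicate D of the second-dose group. Mean negative control counts were 9.38 to 15.8 per tumour, which sets the lowest level that could be measured.

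**Figure D1:**
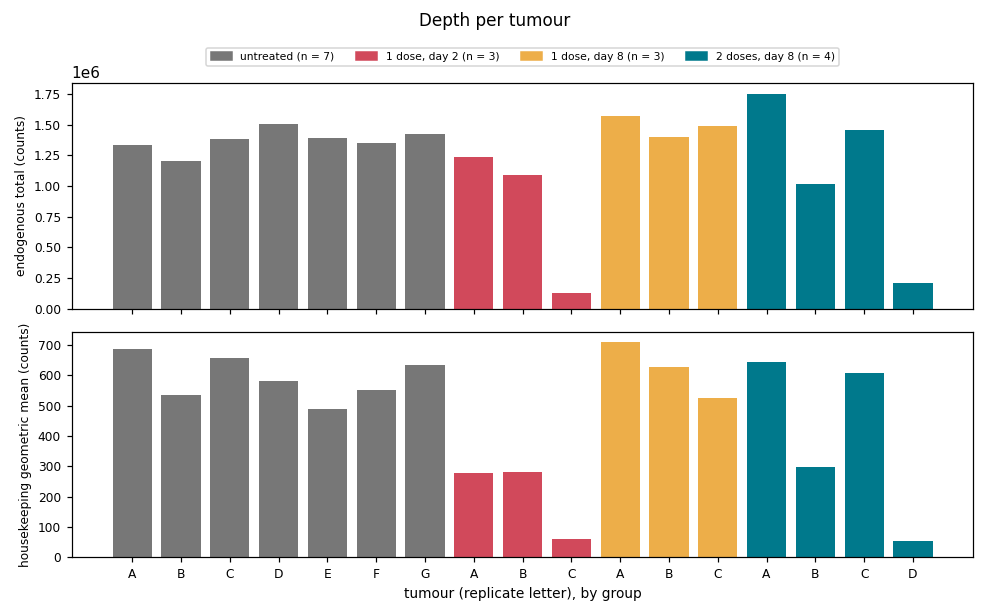
Total endogenous counts (upper panel) and the geometric mean of the 20 housekeeping probes (lower panel) for each tumour, with bars coloured by group and letters giving replicates. Replicate C of the day 2 group (126997 counts) and replicate D of the second-dose group (205118 counts) lie far below the others, and all 3 day 2 tumours have housekeeping means of at most 281 counts.

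Relative to the housekeeping probes, the median tested gene moved by 1.23 log2 at day 2 against untreated, 0.09 at day 8, 0.63 after the second dose and 0.64 over all treated. TMM scaling brought these medians to 0.25, -0.03, -0.05 and 0.05. TMM thus placed genes lower than housekeeping scaling did, so small rises can change direction between the scalings. Within groups, log2 counts of untreated tumours correlated at r = 0.867 to 0.949, day 8 tumours at 0.924 to 0.94 and day 2 tumours at 0.738 to 0.908. In the second-dose group replicates B and D (0.946) and A and C (0.93) were alike, and other pairs gave 0.748 to 0.798.

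The tumours taken 2 days after 1 dose address the early effect of the cytokines. The 10 largest rises included IFNG and genes that it induces. IFNG, the cytokine that IL-12 induces in T and NK cells, rose by 5.58 log2 (SE 0.91, adjusted p = 0.000247 in edgeR). Its normalized count was 414 ± 286 (SD, n = 3) against 8.58 ± 2.19 (n = 7), and it was above background in 0 of 7 untreated tumours, so the fold depends on the background. CXCL10, a chemokine for T cells, rose by 9.41 log2 (SE 1.31), to 89420 ± 85010 counts from 132 ± 179. IDO1, an enzyme that breaks down tryptophan, rose by 9.46 log2 (SE 1.21, adjusted p = 4.35e-05).

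Over all 724 tested genes 346 rose at day 2, and 170 with TMM. Of the 21 interferon-gamma response genes tested, 19 rose (20 adjusted over the list alone) and 18 rose with TMM. The list median was 3.77 log2 (TMM 2.86, adjusted p = 0.000902 by fry). Examples were GBP5, a guanylate-binding protein, at 7.32 log2 (SE 0.96), PSMB8, an immunoproteasome subunit, at 6.09 (SE 0.76), and IRF1, a transcription factor, at 5.43 (SE 0.68). All 11 MHC class I genes rose, also over the list alone and with TMM (median 3.77, adjusted p = 0.000902). All 10 MHC class II genes rose (10 adjusted over the list alone, 8 with TMM, median 3.40, adjusted p = 0.00424), among them the master regulator CIITA at 3.83 (SE 0.57) and DLA-DMB at 4.32 (SE 0.64). None of these lists held its call with an estimated correlation (adjusted p = 0.786 with an estimated correlation for each). Of 11 type I interferon genes 9 rose (10 adjusted over the list alone, 3 with TMM), such as IFI35 at 2.01 (SE 0.39). That list had a median of 1.91, adjusted p = 0.00439, and adjusted p = 0.836 with an estimated correlation.

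Genes of lymphocytes rose as well. GZMB, a granule protease of cytotoxic cells, rose by 6.60 log2 (SE 0.86), GZMA by 3.51 (SE 0.46), and CD8A, the coreceptor of cytotoxic T cells, by 3.34 (SE 0.66, adjusted p = 0.00098). Cytotoxic effector genes rose in 9 of 10 (9 adjusted over the list alone, 6 with TMM, median 2.61, adjusted p = 0.000955). T cell markers rose in 15 of 19 (17 adjusted over the list alone, 11 with TMM, median 2.21, adjusted p = 0.00148), with CD3E, a part of the T cell receptor complex, at 2.89 (SE 0.60) and SH2D1A at 3.67. NK cell markers rose in 9 of 10 (9 adjusted over the list alone, 7 with TMM, median 2.49, adjusted p = 0.000902), with the receptors NCR1 at 3.87 (SE 0.63) and CD160 at 2.58 (SE 0.36). B and plasma cell markers rose in 12 of 13 (13 adjusted over the list alone, 7 with TMM, median 2.36, adjusted p = 0.00148), with MS4A1, the B cell antigen CD20, at 2.79 (SE 0.71) and PAX5, a B cell transcription factor, at 2.37. After background subtraction MS4A1 (adjusted p = 0.124) and PAX5 (adjusted p = 0.0808) were not called. Each of these 4 lists had adjusted p = 0.786 with an estimated correlation.

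The lists nearest to the drug itself also moved. IL-2 and IL-12 pathway genes rose in 15 of 23 and fell in 1 (16 and 1 adjusted over the list alone; 10 and 1 with TMM; median 1.56, adjusted p = 0.0012). EOMES, a transcription factor of effector lymphocytes, rose by 3.99 log2 (SE 0.53), IL2RB, an IL-2 receptor chain, by 3.80 (SE 0.51), and IL2RA by 3.06 (SE 0.83). IL12RB2, an IL-12 receptor chain, did not pass (1.20, SE 0.78, adjusted p = 0.21; 0.05 with TMM). T cell chemokines and receptors rose in 16 of 20 (18 adjusted over the list alone, 11 with TMM, median 2.60, adjusted p = 0.00148), such as CXCL11 at 3.62. Their adjusted p was 0.836 and 0.786 with an estimated correlation.

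Checkpoint and regulatory genes rose in 12 of 21 and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.00732, adjusted p = 0.972 with an estimated correlation), but with TMM 5 rose and 2 fell (median 0.20), and the list was not called (adjusted p = 0.208). CD274, the ligand PD-L1, rose by 3.08 log2 (SE 0.56, adjusted p = 0.000571), PDCD1, its receptor PD-1, by 2.49 (SE 0.54), CTLA4 by 2.19 (SE 0.62) and FOXP3, the regulatory T cell factor, by 1.70 (SE 0.52). Without replicate C of the day 2 group the adjusted p was 0.119 for PDCD1, 0.0916 for CTLA4, 0.524 for FOXP3 and 0.284 for PRF1, the pore-forming perforin, which otherwise rose by 1.27 (SE 0.44). CTLA4, FOXP3 and PRF1 were also not called with TMM. LAG3 (1.06, SE 0.51) and IL10 (0.43, SE 0.43) did not pass.

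Of all 724 tested genes 346 were called higher at day 2. The shares in the checkpoint, dendritic cell, mast cell and complement lists lay near that. Among myeloid lists, dendritic cell markers rose in 6 of 12 (6 adjusted over the list alone, 4 with TMM, median 1.73, adjusted p = 0.00337, adjusted p = 0.883 with an estimated correlation), with XCR1, a receptor of cross-presenting dendritic cells, at 2.70. Mast cell markers rose in 3 of 6 (3 adjusted over the list alone, median 1.98, adjusted p = 0.0364, adjusted p = 0.972 with an estimated correlation), and with TMM 1 rose, 1 fell and the adjusted p was 0.181. The lists of macrophages and monocytes (8 of 18 rose, 8 adjusted over the list alone, adjusted p = 0.0561), neutrophils (3 of 12 rose, 1 adjusted over the list alone, adjusted p = 0.114) and acute inflammation (8 of 19 rose, 8 adjusted over the list alone, adjusted p = 0.0561) were not called. In them C1QA rose by 2.65 log2 and TNF, an inflammatory cytokine, by 2.59, while CD68 (1.15, SE 0.50), CD163 (-0.65, SE 0.74) and CD4 (1.09, SE 0.86) did not pass. Complement genes rose in 12 of 20 (13 adjusted over the list alone; 5 rose and 1 fell with TMM; median 1.68, adjusted p = 0.00285, adjusted p = 0.947 with an estimated correlation), such as C2 at 2.53.

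Genes called lower at day 2 numbered 19 with housekeeping scaling, 114 with TMM, 122 with median-of-ratios scaling and 163 with DESeq2. The 10 named falls were CLDN1, a tight junction protein, by -3.38 log2 (SE 1.14, adjusted p = 0.0225), NCAM1, IL13RA2, TUBB3, THY1, NRP1, FN1, the matrix protein fibronectin, by -1.63 (SE 0.62), ITGB1, LGALS3 and EGFR by -1.25. None of the 10 stayed called without replicate B of the day 2 group, the only myxosarcoma (adjusted p 0.0609 to 0.146). Without the group's replicate C 2 stayed called, and without its replicate A 7 did. Without untreated replicates A, B, C, D, E, F and G in turn, 4, 7, 6, 5, 5, 7 and 7 stayed called. Only THY1 did with sarcoma type as a covariate. Fibroblast and matrix genes fell in 2 of 9 (0 adjusted over the list alone, 6 with TMM, median -1.21, adjusted p = 0.0378, adjusted p = 0.736 with an estimated correlation).

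Apoptosis genes rose in 4 of 12 (4 adjusted over the list alone, median 0.30, adjusted p = 0.00804, adjusted p = 0.836 with an estimated correlation), but with TMM the median was -0.74 with 1 rise and 3 falls. The share of 4 in 12 was under that of all tested genes (346 of 724). FASLG, a death ligand of lymphocytes, rose by 3.53 log2 (SE 0.52). Endothelium and angiogenesis genes rose or fell in 0 of 7 (0 adjusted over the list alone, median -0.10, adjusted p = 0.818) and hypoxia and glycolysis genes in 0 of 3 (0, median -0.21, adjusted p = 0.949), though with TMM both lists were lower (adjusted p = 0.00383 and 0.0285). Each had adjusted p = 0.786 with an estimated correlation. The lists of proliferation (0 of 6 called, median -0.43), pericytes and smooth muscle (0 of 2, 0.41), and skin, fat and skeletal muscle (0 of 4, 0.96) were not called, with 0 adjusted over the list alone. MKI67, a proliferation marker, did not pass (0.68, SE 0.73; -0.46 with TMM). Schwann cell and neural markers had 1 rise and 1 fall in 5 (2 and 1 adjusted over the list alone, adjusted p = 0.103).

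In all, edgeR called 365 of 724 genes at day 2, 346 higher and 19 lower. With TMM the count was 284, 170 higher and 114 lower, and 154 genes rose and 19 fell under housekeeping, TMM and median-of-ratios scaling alike. With sarcoma type as a covariate 211 genes were called, and with peripheral nerve sheath tumours only 37, where 249 had an unadjusted p under 0.05. There 333 of 333 rises measured were still higher, at a median of 2.21 log2 (2.29 for the rises in all tumours), from tumours that also helped to pick them. Scores per tumour rose for 15 of 25 lists with housekeeping scaling and for 9 with TMM, which lowered 2. The interferon-gamma score was 11.76 ± 0.72 (n = 3) against 7.47 ± 0.80 (n = 7), higher than every untreated tumour in 3 of 3 (exact permutation p = 0.00833, the smallest such a test can give; adjusted p = 0.0245).

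**Figure D2:**
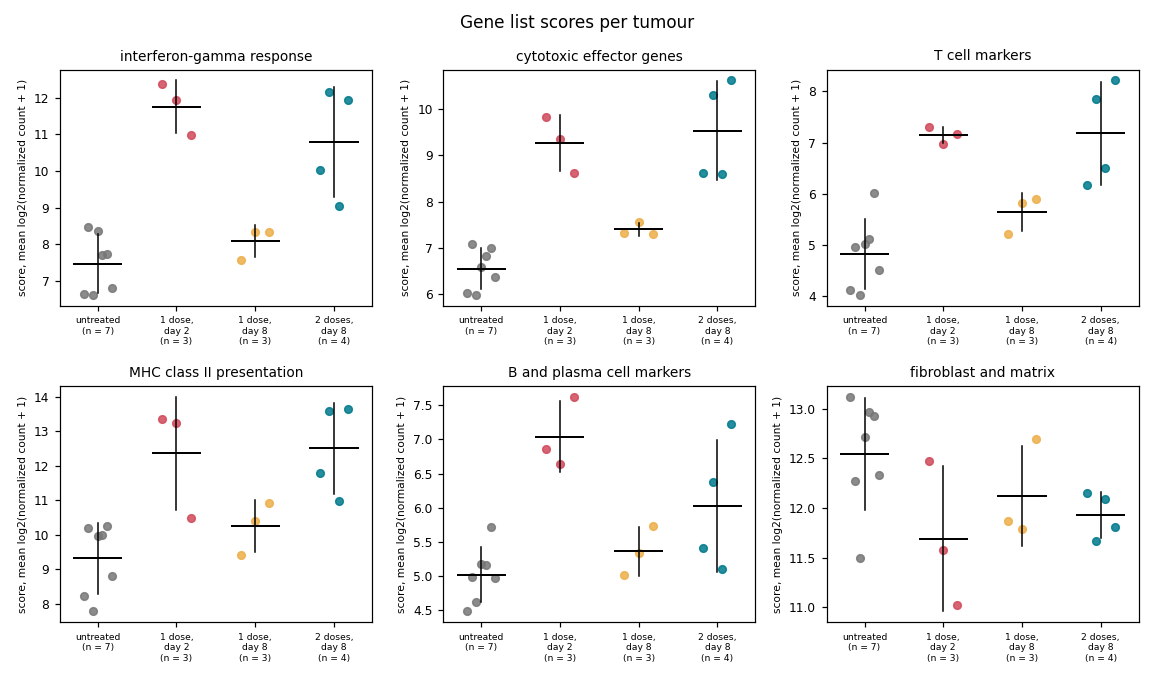
Scores of 6 gene lists (mean log2(normalized count + 1), vertical axes) for the 4 groups, with 1 dot per tumour, a horizontal line for the mean and a vertical line for 1 SD on either side. Interferon-gamma scores average 11.76 at day 2 and 10.79 after the second dose against 7.47 in untreated tumours, while the day 8 tumours reach at most 8.34.

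The tumours taken 8 days after 1 dose ask how much of the change remained. IFNG was at 11.1 ± 3.57 normalized counts (SD, n = 3), near the 8.58 ± 2.19 (n = 7) of untreated tumours, and above background in 0 of 3. CXCL10 (-0.35 log2, SE 1.17) and CD274 (-0.59, SE 0.61) lay near untreated, and GZMB (1.82, SE 0.79), GZMA (1.04, SE 0.46), CD3E (1.52, SE 0.60) and CD8A (1.44 with TMM) somewhat above, none past the test (adjusted p = 0.984 in edgeR). CD160, an NK and T cell receptor, came closest (1.76, SE 0.35, adjusted p = 0.0787), then CD96 (1.83, SE 0.51) and TRGC3, a gamma T cell receptor chain (1.37, SE 0.39). Lowest by p were BCL6 (-1.14), KIT (-2.44, SE 1.04) and ITGA5 (-0.90). FOXP3 (0.22), NCR1 (0.93), IDO1 (1.03), CD68 (0.17), CD163 (0.31) and LAG3 (0.75) did not pass either.

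EdgeR called 0 of 724 genes at day 8, with 33 at an unadjusted p under 0.05. DESeq2 called 0 (72 unadjusted) and limma on the deposited values called 0 (34 unadjusted). Of the 25 lists 0 were called by fry, the nearest being NK cell markers (median 0.93, adjusted p = 0.0533; 0 of 10 genes, 2 adjusted over the list alone). The NK list was called with TMM (adjusted p = 0.0275), and cytotoxic effector genes were too (median 0.79, adjusted p = 0.126, with TMM 0.0338). Each had adjusted p = 0.786 with an estimated correlation. The NK score was higher, 5.67 ± 0.15 (n = 3) against 4.87 ± 0.25 (n = 7), above every untreated tumour in 3 of 3 (exact permutation p = 0.00833, adjusted p = 0.0245). The cytotoxic score was also above every untreated tumour in 3 of 3 (difference 0.85, exact permutation p = 0.025, adjusted p = 0.061; with TMM adjusted p = 0.026). T cell markers (median 0.69), MHC class I (0.86) and MHC class II genes (0.80) were not called.

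The second-dose tumours were taken on day 8, 2 days after the last dose. GZMB rose most, by 8.30 log2 (SE 0.90, adjusted p = 1.64e-05 in edgeR), to 8430 ± 9297 normalized counts (SD, n = 4) from 26.6 ± 13.4 (n = 7). IDO1 rose by 8.26 (SE 1.14), CXCL10 by 7.77 (SE 1.22), GBP5 by 7.21 (SE 0.94) and IFNG by 6.64 (SE 0.92), to 876 ± 977 counts from untreated counts at background. ACOD1, a macrophage enzyme that makes itaconate, rose by 5.85, CCL8, a monocyte chemokine, by 5.80, IFGGC1 by 5.68, IGHM, the heavy chain of IgM, by 5.15 (SE 0.86), and SLAMF6, a lymphocyte receptor, by 4.98 (SE 0.82).

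Lists of antigen presentation and of T, NK and cytotoxic cells were called higher after the second dose, where 241 of all 724 tested genes rose. Interferon-gamma response genes rose in 19 of 21 (19 adjusted over the list alone, 18 with TMM, median 3.19, adjusted p = 0.00317), MHC class I in 11 of 11 (11 and 10, median 3.06, adjusted p = 0.00278) and MHC class II in 10 of 10 (10 and 10, median 3.35, adjusted p = 0.00439). Cytotoxic effector genes rose in 9 of 10 (9 adjusted over the list alone, 7 with TMM, median 3.28, adjusted p = 0.000955), T cell markers in 16 of 19 (16 and 13, median 2.46, adjusted p = 0.00175) and NK cell markers in 7 of 10 (7 and 6, median 2.72, adjusted p = 0.000955). GZMA rose by 4.03 log2 (SE 0.44), CD3E by 3.23 (SE 0.58), CD8A by 3.63 (SE 0.63), NCR1 by 3.66 (SE 0.60) and CD160 by 3.11 (SE 0.33). T cell chemokines and receptors rose in 13 of 20 (13 adjusted over the list alone, 11 with TMM, median 2.51, adjusted p = 0.00525), with CXCR6, a homing receptor, at 3.55. Each of these 7 lists had adjusted p = 0.786 with an estimated correlation.

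IL-2 and IL-12 pathway genes rose in 11 of 23 (12 adjusted over the list alone, 11 with TMM, median 1.88, adjusted p = 0.00439, adjusted p = 0.79 with an estimated correlation), with EOMES at 4.25 log2 and IL2RB at 3.98. IL12RB2 did not pass (1.88, SE 0.72, adjusted p = 0.0531). Dendritic cell markers rose in 5 of 12 (6 adjusted over the list alone, 3 with TMM, median 1.55, adjusted p = 0.0212, adjusted p = 0.883 with an estimated correlation). Type I interferon genes rose in 5 of 11 (6 adjusted over the list alone, 1 with TMM, median 1.31, adjusted p = 0.0324, adjusted p = 0.883 with an estimated correlation) and complement in 7 of 20 (7 and 6, median 0.73, adjusted p = 0.0378, adjusted p = 0.988 with an estimated correlation). With TMM these last lists were not called (adjusted p = 0.111 and 0.137).

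Lists not called after the second dose were B and plasma cell markers (6 of 13 rose, 6 adjusted over the list alone, median 1.44, adjusted p = 0.0533), checkpoint and regulatory genes (8 rose and 1 fell, 9 and 1 adjusted over the list alone, median 0.72, adjusted p = 0.0516) and macrophages (7 of 18 rose, 10 adjusted over the list alone, adjusted p = 0.0568). Neutrophil markers (6 of 12 rose, 6 adjusted over the list alone, adjusted p = 0.103), acute inflammation (10 of 19 rose, 11 adjusted over the list alone, adjusted p = 0.0561), mast cell markers (2 of 6 rose, 2 adjusted over the list alone) and fibroblast and matrix genes (median -0.79, adjusted p = 0.126, with TMM lower at adjusted p = 0.0202, adjusted p = 0.786 with an estimated correlation) were not called either. CD274 rose by 2.88 log2 (SE 0.53) and CTLA4 by 2.48 (SE 0.58). PDCD1 (0.47, SE 0.53; -0.27 with TMM), FOXP3 (0.38, SE 0.50; -0.27 with TMM), LAG3 (0.57; -0.17 with TMM), MS4A1 (1.44, adjusted p = 0.134), CD163 (-0.33) and MKI67 (1.03) did not pass. CD4 rose by 3.12 (SE 0.78), CD68, a macrophage protein, by 1.62 (SE 0.46) and IL2RA by 2.77 (SE 0.79), but without replicate B of the second-dose group their adjusted p was 0.0869, 0.104 and 0.074. CD68 was also not called with TMM (0.89, adjusted p = 0.0842), median-of-ratios scaling or DESeq2, and neither CD68 nor IL2RA was with sarcoma type as a covariate. PRF1 rose by 1.49 (SE 0.41), with adjusted p = 0.118 without replicate D, and not with TMM (0.62).

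EdgeR called 244 genes after the second dose, 241 higher and 3 lower. The falls were BRCA2 (-0.99 log2), CD276 (-0.82) and ATG16L1 (-0.81). Of these, 0 stayed called without replicate D of the second-dose group, the only fibrosarcoma. Without the group's replicate B 1 stayed called, and without its replicates A and C in turn 2 did. Without untreated replicate A 1 stayed called, and without B, C, E, F or G 2 did. None of the 3 was called with sarcoma type as a covariate. With TMM 192 genes were called, 156 higher and 36 lower, and 145 genes rose under housekeeping, TMM and median-of-ratios scaling alike. Without replicate B of the second-dose group 152 genes were called. With sarcoma type as a covariate the count was 135, and with peripheral nerve sheath tumours only edgeR called 0, with 148 at an unadjusted p under 0.05. In those tumours 237 of 237 rises measured were still higher, at a median of 2.02 log2 (2.51 for the rises in all tumours), but the same tumours helped to pick them. The interferon-gamma score was 10.79 ± 1.51 (n = 4), above every untreated tumour in 4 of 4 (exact permutation p = 0.00303, the smallest such a test can give; adjusted p = 0.0197).

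**Figure D3:**
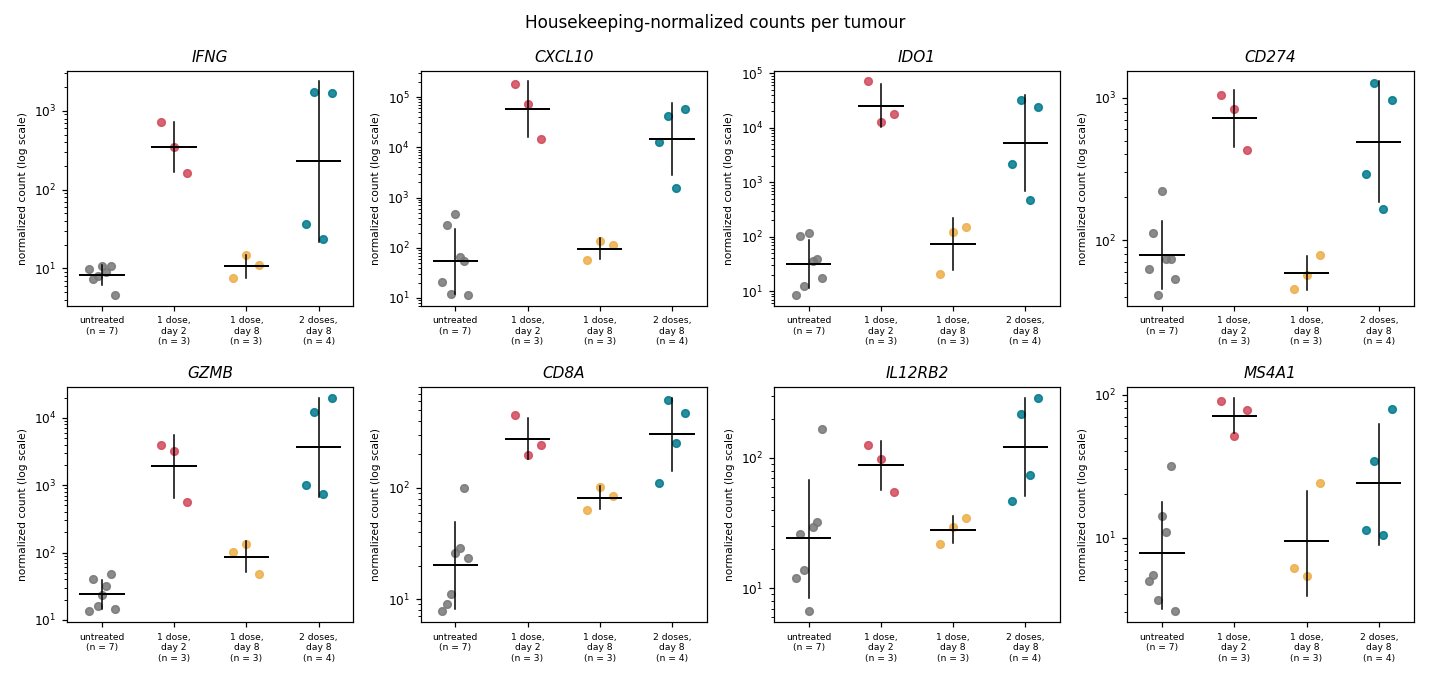
Housekeeping-normalized counts (log axes) of 8 genes in the 4 groups, with 1 dot per tumour and lines for the mean and 1 SD on either side of log2(count + 1). The arithmetic mean of IFNG, which is not the line drawn, is 414 counts at day 2 and 876 after the second dose against 8.58 in untreated and 11.1 in day 8 tumours.

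The mean of the 3 treated groups, weighted equally, was compared with untreated; it includes the day 8 group, in which 0 genes were called. IDO1 rose by 6.25 log2 (SE 1.01), CXCL10 by 5.61 (SE 1.06), GZMB by 5.57 (SE 0.77), GBP5 by 4.95 (SE 0.81), IFNG 18.3-fold, SLAMF6 by 4.07 and PSMB8 by 3.91. KIT, a receptor of mast cells and some tumours, was the largest fall (-2.04, SE 0.65, adjusted p = 0.0244 in edgeR), and it was not called without untreated replicate F or G. The other falls were EGFR (-1.01), PPARG (-0.88), ITGA5, CD276, ATRX, BRCA2, KMT2A, ATG16L1 and TSC2 (-0.60). Of the 10 falls, 5 stayed called without untreated replicate F, 6 without A, C, E or G, 7 without B, 9 without D, and 4 without replicate B of the day 8 group. For the other treated replicates left out in turn, 7 to 9 stayed called. Only KIT did with sarcoma type as a covariate, but KIT was not called without the 2 shallow libraries (-1.96 log2, adjusted p = 0.0735), in limma on the deposited values (-0.96, adjusted p = 0.259) or in peripheral nerve sheath tumours only (-2.84, adjusted p = 0.202).

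Lists called for all treated were 14 higher and 1 lower. The interferon-gamma response (18 of 21 rose, 19 adjusted over the list alone, median 2.49, adjusted p = 0.00175), cytotoxic effectors (7 of 10, 9 alone, median 2.34, adjusted p = 0.000955) and T cell markers (14 of 19, 16 alone, median 1.86, adjusted p = 0.00175) were among them. B and plasma cells (6 of 13, 8 alone, median 1.40, adjusted p = 0.0111) and macrophages (6 of 18, 10 alone, median 1.04, adjusted p = 0.0425) were as well, though with TMM the macrophage list was not (adjusted p = 0.186). NK cells, dendritic cells, checkpoint and regulatory genes, type I interferon, MHC class I and class II, the IL-2 and IL-12 pathway, T cell chemokines and complement were the others that were higher. With TMM the checkpoint list (adjusted p = 0.243) and the type I interferon list (0.0845) were not called. Fibroblast and matrix genes were lower as a list (median -0.82, adjusted p = 0.0375; 0 of 9 genes fell, 5 with TMM). With an estimated correlation the adjusted p of the 15 lists was 0.736 to 0.968. EdgeR called 225 genes, 215 higher and 10 lower. With TMM it called 237, 149 higher and 88 lower, with sarcoma type as a covariate 87, and with peripheral nerve sheath tumours only 0, with 130 at an unadjusted p under 0.05.

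Day 8 against day 2 of a single dose tested the change with time. The largest falls were in CXCL10 (-9.75 log2, SE 1.97, adjusted p = 0.00988 in edgeR), IDO1 (-8.43, SE 1.72), GBP5 (-6.99, SE 1.37), ACOD1 (-6.74, SE 1.21) and CCL8 (-6.49, SE 1.36). Interferon-gamma response genes fell in 15 of 21 (19 adjusted over the list alone, 13 with TMM, median -3.38, adjusted p = 0.00732), MHC class I in 6 of 11 (10 and 6, median -2.65, adjusted p = 0.015), T cell chemokines in 7 of 20 (15 and 2, median -2.72, adjusted p = 0.0206) and the IL-2 and IL-12 pathway in 11 of 23 (14 and 5, with 1 rise in each, median -1.72, adjusted p = 0.013). Cytotoxic effectors fell in 4 of 10 (7 and 4, median -2.20, adjusted p = 0.0188), B and plasma cell markers in 6 of 13 (10 and 0, median -2.05, adjusted p = 0.0169) and NK cell markers in 4 of 10 (6 and 1, median -1.74, adjusted p = 0.0212, with TMM 0.18). Type I interferon (4 of 11, median -1.79, with TMM adjusted p = 0.169), complement (4 of 20, median -1.46, with TMM 0.312) and apoptosis genes (4 of 12, median -0.50, with TMM 0.39 and adjusted p = 0.655) were also lower, with 5, 4 and 4 genes adjusted over the list alone. With an estimated correlation the adjusted p of the 10 lists was 0.786 to 0.982.

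CLDN1 (3.85 log2, SE 1.24) and IL13RA2 (3.16, SE 1.07) rose from day 2 to day 8. EdgeR called 142 genes, 3 higher and 139 lower. With TMM it called 81, 27 higher and 54 lower, and 51 falls held under housekeeping, TMM and median-of-ratios scaling. Without replicate A, B or C of the day 8 group the counts were 0, 0 and 1, where the adjusted p of the 5 named falls was 0.052 to 0.0917, and without replicate C of the day 2 group the count was 76. CLDN1 and IL13RA2 were not called once any of replicates A, B and C of the day 2 group or A, B and C of the day 8 group was left out (adjusted p 0.0525 to 0.119). With sarcoma type as a covariate 76 genes were called and with peripheral nerve sheath tumours only 0, with 144 at an unadjusted p under 0.05.

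The second dose against day 8 of 1 dose compared tumours at the same time after the first dose. CXCL10 was higher by 8.12 log2 (SE 1.82, adjusted p = 0.0182 in edgeR), IDO1 by 7.23 (SE 1.61), GBP5 by 6.88 (SE 1.35), CCL8 by 6.62 (SE 1.35) and GZMB by 6.49 (SE 1.22). Interferon-gamma response genes were higher in 11 of 21 (18 adjusted over the list alone, 9 with TMM, median 2.50, adjusted p = 0.0318, adjusted p = 0.786 with an estimated correlation) and cytotoxic effectors in 5 of 10 (8 and 5, median 2.22, adjusted p = 0.0134, adjusted p = 0.786 with an estimated correlation). IL-2 and IL-12 pathway genes were higher in 6 of 23 (11 and 6, TMM median 0.70, adjusted p = 0.0378, adjusted p = 0.79 with an estimated correlation) and NK cell markers in 2 of 10 (6 and 0, median 1.44, adjusted p = 0.0455, with TMM 0.111, adjusted p = 0.811 with an estimated correlation). EdgeR called 68 genes, all higher, and with TMM 48 higher and 8 lower. With only the groups compared in the model it called 0 (193 at an unadjusted p under 0.05), and without the 2 shallow libraries 0 (175). Without replicate A, B or C of the day 8 group 0 genes were called, without replicates B and D of the second-dose group 11 and 13, and without its replicates A and C 165 and 191. With sarcoma type as a covariate 28 genes were called and with peripheral nerve sheath tumours only 0, with 74 at an unadjusted p under 0.05.

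The second dose against day 2 of 1 dose compared tumours 2 days after their last dose. IL32, a lymphocyte cytokine, was lower (-3.68 log2, SE 0.76, adjusted p = 0.0688 in edgeR), as were IFNA7, a type I interferon (-4.33, SE 0.91, adjusted p = 0.0688), and NCR3, an NK receptor (-2.57, SE 0.60, adjusted p = 0.089), none past the test. Highest by p were CXCR4 (1.65, SE 0.60), CLDN1 (3.13, SE 1.17) and IGHM (2.49, SE 1.07). EdgeR called 0 genes, with 88 at an unadjusted p under 0.05, DESeq2 called 6 (113 unadjusted) and limma on the deposited values called 1 (97 unadjusted). Without replicate A of the day 2 group edgeR called 28, without its replicate B 3, and without replicate B of the second-dose group 1. No list was called, and the interferon-gamma list had a median of -0.55 (adjusted p = 0.354).

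**Figure D4:**
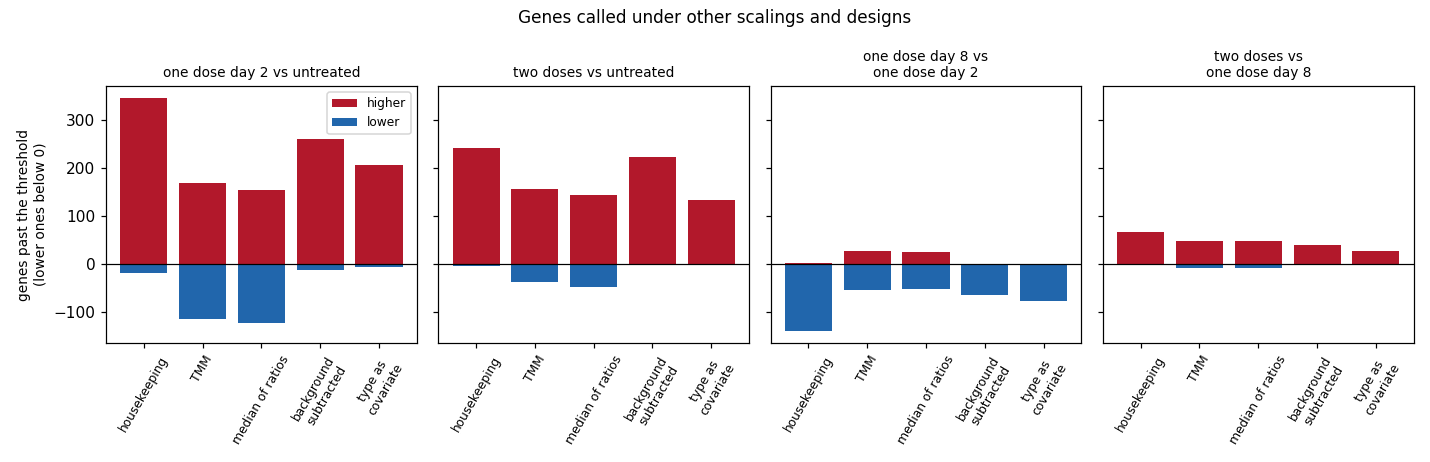
Numbers of genes called (vertical axis, genes lower in the first group drawn below 0) in 4 comparisons under housekeeping, TMM and median-of-ratios scaling, background subtraction, and sarcoma type as a covariate. At day 2 the genes called higher go from 346 with housekeeping scaling to 170 with TMM, and those called lower from 19 to 114.

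Day 2 and second-dose tumours were compared with the same 7 untreated tumours, so their changes share an error. Genes called higher in both numbered 219, where independence would give 115, and 1 was lower in both (0.0787). Across genes, which are not independent replicates, the fold changes had r = 0.825 and a covariance of 1.92. In 20 simulations with no change but shared controls the overlap was 0, r was 0.305 and the covariance 0.12. With no change simulated almost no gene is called, so that overlap was fixed in advance and sets no measure for the 219. With the untreated tumours split between the comparisons, 84 genes were higher in both (of 212 and 120), with r = 0.747 and a covariance of 1.87. With the parts exchanged 4 were higher in both (of 237 and 4), with r = 0.702 and a covariance of 1.81.

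Perivascular wall against peripheral nerve sheath tumours, both untreated, gave the background of type. KIT was lower in perivascular wall tumours (-3.20 log2, SE 0.86), as was ZEB1 (-1.46, SE 0.41), and KRT7, a keratin (1.47, SE 0.38), IL3RA (1.36, SE 0.38) and S100A8 (2.56, SE 1.00) were higher, none past the test (adjusted p = 0.998 in edgeR). EdgeR called 0 of 676 genes, with 27 at an unadjusted p under 0.05, DESeq2 called 4 (54 unadjusted) and limma on the deposited values called 0 (21 unadjusted). Without untreated replicate B edgeR called 1.

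For some lists that were not called, the median, the mean and the fry test differed in sign. These were proliferation and Schwann cell markers at day 8 against untreated and in second dose against day 8, and Schwann cell markers after the second dose. Skin, fat and skeletal muscle markers did so after the second dose, over all treated, and in second dose against day 2. So did hypoxia genes over all treated and in day 8 against day 2, and macrophage markers in second dose against day 2.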

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

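The other scalings, background subtraction and the settings by sarcoma type were planned, but their use as tests of these explanations, and the splits of samples into chance groups, were chosen only after the results were seen. Chance picks about 1 in 20 groups for an unusual sample, and 4 were found in 112 groups tested.

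At day 2 the rise reached 346 of 724 genes, and libraries with few housekeeping counts may raise every gene. Housekeeping scaling alone could not account for 154 of these, also called with TMM and median-of-ratios scaling. Nor could the difference of perivascular wall from other tumours account for 206 called with type as a covariate. After subtraction of the negative control mean 257 stayed called, but some of these lay at or under background in a day 2 tumour. Background alone could not account for the others of the 257. Scaling stays open for the rises lost under other scalings (median 0.84 log2 with TMM, SD 0.47), and type for those lost with the covariate, since the median of all rises in peripheral nerve sheath tumours only (2.21 log2, SD 1.19) comes from tumours that helped to pick them. Of the 346 rises 111 lay at or under background in a day 2 tumour, and background stays open for them. Among the 89 rises lost after subtraction were 65 of the 111, and why the rest of the 89 were lost was not tested. Archiving of the untreated tumours went with treatment in every comparison with untreated and was not tested as a cause. Negative controls over housekeeping, which the main test did not subtract, were 1.98 log2 higher at day 2 than in untreated tumours (SD 1.21, n = 3), at -1.57 in replicate A, -1.16 in B and 0.69 in C, the library with few counts, against an untreated mean of -2.66. They were 1.22 log2 higher after the second dose (SD 1.55, n = 4), with 0.76 in replicate D, and 0.31 higher at day 8 (SD 0.23, n = 3).

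Interferon-gamma response genes were high at day 2 and after the second dose, and near untreated at day 8 of 1 dose. A difference between reagent lots could not give this pattern alone, since the list median changed by -3.38 log2 from day 2 to day 8, where no probe factors were found in either group. Housekeeping scaling could not either (-2.47 with TMM), nor could 1 extreme tumour, since the lowest day 2 score was 2.63 above the highest day 8 score. That gap lay between treated groups, so for this list it also argues against archiving of the untreated tumours as the only cause. The time since the last dose may set the level: second-dose and day 2 tumours, both 2 days after a dose, differed by -0.55 log2 (adjusted p = 0.354). That a list did not pass does not show equal levels, and the time since the last dose, the number of doses and the dogs stay open as untested.

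B and plasma cell markers were higher at day 2. The list was still called by fry after background subtraction (adjusted p = 0.000684), but MS4A1 and PAX5 were not called in edgeR then (adjusted p = 0.124 and 0.0808). Some members can carry a fry call, so background stays open for members near it. The score was highest in replicate C (7.63), the library with few counts. Replicates A (6.87) and B (6.63) also lay above the untreated tumours (4.48 to 5.71). Housekeeping scaling (adjusted p = 0.00383 by fry with TMM) and a reagent lot (list median -2.05 log2 from day 2 to day 8) could not alone account for the call of the list. Whether the rise reflects B cells that entered the tumour, or lymphoid tissue taken with it, may not be told from counts of whole tissue. With an estimated correlation the list had adjusted p = 0.786.

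The change from untreated differed between day 8 and day 2 of 1 dose for 142 genes and 10 lists, by a direct test of those groups, though none of the 10 lists was called with an estimated correlation (adjusted p 0.786 to 0.982). It differed between the second dose and day 8 of 1 dose for 68 genes and 4 lists by the same test, and none of these 4 was called with an estimated correlation (adjusted p 0.786 to 0.811). B2M was 5.42% of endogenous counts in untreated replicate B, where the other untreated tumours had 0.687% to 2.04%. Untreated replicate D had a neutrophil score of 8.59 (others 5.06 to 5.92) and an acute inflammation score of 8.65 (others 5.30 to 6.41). FOXP3 was at 61.5 normalized counts in replicate D of the second-dose group, a library with few counts, against 27.8 to 29.4 in the others. Its raw count in replicate D was under that sample's negative control mean of 11.6, so FOXP3 was not detected there and the high value came from the scaling.

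For day 2 against untreated 100 of 120 splits were run, and only the real one called as many as 365 genes (highest other 155). Chance groups among those run thus did not reach it. For the second dose 100 of 330 were run, and only the real one called as many as 244. The highest other called 241, so a split not run could reach 244. Every other split run with 131 calls or more kept second-dose replicates B and D together. For all treated 100 splits were run, and only the real one called as many as 225 (highest other 142). Chance groups could not be excluded for second dose against day 8 (68 genes, 5 of 35, highest other 220). Where 0 genes were called every split has as many, so the splits decide nothing for day 8 against untreated (100 of 100; highest other 2), second dose against day 2 (35 of 35; highest other 99) or tumour type (35 of 35; highest other 49). For day 8 against day 2 the 10 splits are too few for a share under 0.05 (142 genes, 1 of 10; highest other 0). In second dose against day 8, the other splits with more calls than the real 68 (146 to 220) kept second-dose replicates B and D together. Untreated replicates A, C and G set apart called 49 genes for tumour type and 155 among day 2 and untreated tumours. Both point to a structure of the samples.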

How the results depend on the processing

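Each treated group held 3 or 4 tumours of different dogs. Counts of genes moved with the setting, and the cause was not tested. With TMM day 8 against day 2 gave 81 genes and with median-of-ratios scaling 76, where housekeeping scaling gave 142. After background subtraction it gave 64, and second dose against day 8 gave 41 where it had given 68. With no filter and with filterByExpr, second dose against day 2 went from 0 to 3 genes. With sarcoma type as a covariate the counts were 211 for day 2, 135 for the second dose, 87 for all treated, 76 for day 8 against day 2 and 28 for second dose against day 8. With peripheral nerve sheath tumours only they were 37, 0, 0, 0 and 0, from fewer samples. With only the groups compared in the model, second dose against day 8 gave 0. Without the 2 shallow libraries it gave 0, and day 8 against day 2 gave 92. DESeq2 called 6 genes for second dose against day 2, 123 for second dose against day 8 and 4 for tumour type, and limma on the deposited values called 1, 16 and 0. The lists called fell from 56 to 35 with sarcoma type as a covariate, and to 0 with peripheral nerve sheath tumours only or with camera and an estimated correlation. With camera and the preset correlation 53 were called, 32 of them among the 56.

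MCAM at day 2 changed sign, from 0.11 log2 to -0.92 with TMM, -1.01 with median-of-ratios scaling in edgeR and -1.01 in DESeq2. With 1 sample left out in turn, counts ranged from 260 to 364 for day 2, 152 to 286 for the second dose, 184 to 269 for all treated and 0 to 0 for day 8. They ranged from 0 to 132 for day 8 against day 2, 0 to 28 for second dose against day 2, 0 to 191 for second dose against day 8 and 0 to 1 for tumour type. A count was taken as the same when it lay within a ratio of 1.5 of the main count or when both were 0. By that rule 284 genes with TMM at day 2 were the same as 365, though the directions shifted. Over all settings 145 of 189 counts stayed the same, 32 were weaker and 12 stronger. Named genes were judged by their call, not by the size of the change. Of 8163 cases 7395 kept their call or their lack of one, 616 lost a call and 148 gained one. The other 4 changed sign with a call in at least 1 of the settings. A model with the cartridge was not run, because the files name none.

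The labels give groups the same replicate letters, but the tumours came from different dogs and the letters do not pair. Samples with the same letter correlated at a mean of r = 0.0892 after group means were removed, and other samples at -0.0203. Of 17 samples 8 were most like one with their own letter, and untreated replicates E, F and G had no other sample with theirs. How many would be so by chance was not worked out, so these values do not show an absence of pairing. With the letter as a replicate block the counts were 335 for day 2, 197 for the second dose, 207 for all treated, 145 for day 8 against day 2 and 0 for second dose against day 8. KIT in all treated went from -2.04 log2 to 0.27 with the replicate block.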

Other observations

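The genes in the next lines were chosen after their values were seen, so their adjusted p values in edgeR describe and do not test them. SAA1, an acute-phase protein, was higher by 4.13 log2 (SE 0.71, adjusted p = 0.000392) at day 2 and by 4.28 (SE 0.69, adjusted p = 0.000224) after the second dose. It was 0.30 (SE 0.75, adjusted p = 0.984) at day 8 of 1 dose. NOS2, the inducible nitric oxide synthase, was higher by 3.42 (SE 0.65) at day 2 and 2.19 (SE 0.61) after the second dose, though not with TMM after the second dose (1.22, adjusted p = 0.0889). IL15, a cytokine for NK and memory T cells, was higher by 2.90 (SE 0.35) and 2.19 (SE 0.33). SOCS1, a brake on cytokine signalling, was higher by 3.42 (SE 0.54) and 2.87 (SE 0.51), and CD38 by 3.59 (SE 0.63) and 3.34 (SE 0.60).

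IL32 was higher at day 2 (4.14 log2, SE 0.62) at 614 ± 475 normalized counts (SD, n = 3) against 34.6 ± 11.9 in untreated tumours (n = 7), and was 45.5 ± 47.9 (n = 4) after the second dose. The direct comparison of second dose with day 2 did not pass for IL32 (-3.68, SE 0.76, adjusted p = 0.0688 in edgeR). IFNA7 was higher at day 2 by 4.89 log2 (SE 0.73) but was above background in 3 of 7 untreated tumours and 2 of 3 day 2 tumours.

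In the second-dose group the interferon-gamma score was 12.15 in replicate B, 11.94 in D, 10.03 in A and 9.04 in C. The untreated tumours had 6.61 to 8.47. Replicates B and D had the lower housekeeping means of the group (297 and 55.1 counts) and A and C the higher (643 and 608), so housekeeping counts and the score were not separate. Their positive control means were also lower (311 and 69.8, against 965 and 1243). Housekeeping over positive controls was 0.955 in B and 0.789 in D, and 0.666 in A and 0.489 in C. Less RNA in second-dose replicates B and D was therefore not shown. In the day 2 group the same ratio was 0.79 in replicate A, 0.144 in B and 0.0277 in C. It was 0.415 to 0.498 in the day 8 group and 0.64 to 1.12 in untreated tumours. Day 2 replicates B and C thus had few housekeeping counts for their positive controls. POS_A, the brightest positive control, ran from 1243 counts in replicate D of the second-dose group to 69767 in replicate C of the day 2 group, and was not used to scale.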
